A study of Mus musculus with 8 samples.

How the data were processed

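Mouse ES cells, which derive from the early embryo and can form all its lineages, were sampled on 8 arrays, 4 after 8 h with 2.5 µM cisplatin and 4 after the solvent dimethyl sulfoxide. Per the labels' protocols, the cells were passaged on feeder-coated and then on gelatin-coated plates, total RNA was extracted with a column kit that keeps small RNA, and the messenger RNA was amplified and labelled with biotin by a kit that primes at the 3′ end. Such arrays read mostly the 3′ end of polyadenylated transcripts, so transcripts without a poly(A) tail are read poorly and a change in transcript length outside the probes is not seen. The authors deposited 1 table of log2 expression values, 1 column per array, which the submitters' processing notes attribute to RMA; the same notes name limma. RMA corrects background, normalizes between arrays and summarises the probes of a probe set on the log2 scale; versions are not given in the sources used here. Normalization between arrays assumes that most transcripts keep their level, so a change of total RNA per cell would not be seen. The quartiles of the columns nearly coincide, with medians from 3.35 to 3.38.

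The table holds 45141 probe sets, of which 104 are controls. In the platform annotation, 28898 probe sets have 1 gene, 551 have several and 15588 besides the controls have none listed; the last 2 kinds were left out of the gene tests. Genes are written by the current symbol found through their Entrez identifier in a RefSeq table of the mouse assembly GRCm38.p6, which held 16937 of the 17098 genes. The same table gave the gene lengths, used only as a property of the gene, since no genome build belongs to the array values. For each gene the probe set with the highest mean over all 8 arrays was used. Of the called genes 1744 had more than 1 probe set, and for 9 of them another probe set passed the test in the opposite direction.

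The groups come from the treatment label of each sample. Cisplatin was compared with control by limma 3.58.1 (lmFit and eBayes with default settings, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment over the 17098 genes and a threshold of 0.05. A change of at least 1 on the log2 scale was called 2-fold. No filter on dim genes was applied. Array background was read from probes of 25 bases with 24 G or C that match no transcript, at 3.10 on the log2 scale. Such probes with 5 or 17 G or C lay lower, at 2.10 and 2.44, so a gene under 3.10 can still carry signal. In both groups 5359 genes lay below 3.10, and 78 of these were called. Values are given as log2 fold change (cisplatin minus control) ± SE over 4 arrays per group, and group levels as mean ± SD.

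Before the data were examined, 25 gene lists were written from textbook knowledge and tested against all other genes with camera (preset correlation of 0.01), with an estimated correlation and with fry beside it, each adjusted over the 25 lists. The named genes follow a rule fixed at the same time. It takes the 8 largest increases and the 8 largest decreases among called genes whose groups do not overlap, skipping predicted genes and clones (1 was skipped among the increases), the 4 members of each list with the smallest p, and Hprt, Trp53, Mdm2, Cdkn1a, Pou5f1, Nanog and Sox2. Where 5 or fewer members of a list were called in a direction, the remaining ones were named as well, chosen after their values were seen: Xpc, Gtf2h5, Fancc, Rad51c, Prim2, Lefty1, Lefty2, Cebpb, Slc7a5, Herpud1 and Klf6. Control probe sets, spike-ins and list means were compared by two-sided exact permutation tests over the 70 assignments of the arrays. For 108 of the 109 named genes that were called, those of the closing section included, the groups did not overlap. The rule itself requires this of the largest changes, and it held for 3087 of all 3303 called genes.

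The test was tested on simulated data with the means and spreads of the 17098 genes and 200 changed genes. Of 100 genes set to a log2 change of 1 in size 99 were recovered, and of 100 set to 0.5 in size 61, with 8 false calls. The 200 changed genes are a far smaller share than the 19.3% of genes called in the data, so these counts need not hold there. A simulated list of 30 shifted genes passed camera's threshold and an unchanged list did not. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.

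Alternatives covered the choice of probe set, dim genes, normalization, centring, the settings of the test, the threshold, a term for the replicate number and each array left out in turn. After the data were seen, lists of ATF4 targets, of Hedgehog and Wnt signalling genes and of epidermal and epithelial barrier genes were added, and alternatives without probe sets that can match several transcript families and without genes over 100 kb. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.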

Results

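The series profiled mouse embryonic stem (ES) cells, described in the labels as HPRT deficient and of strain C57BL/6 at passages 19 to 22, after 8 h with 2.5 µM cisplatin or with the solvent dimethyl sulfoxide. Cisplatin is a platinum drug that forms crosslinks within and between DNA strands. The study as a whole set out to read coding and noncoding RNA of these cells together by sequencing, and these arrays are its microarray arm. Total RNA from 4 treated and 4 solvent samples was hybridised to 1 array each, and the replicates carry the numbers 3 to 6 in both groups. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 4 arrays per group limit the precision, and the median standard error of a log2 fold change was 0.08.

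The arrays within a group correlated at 0.997 to 0.998 over the 17098 genes tested, each read by 1 probe set, and arrays of different groups at 0.992 to 0.995. The largest principal component held 56.7% of the variance and separated the groups. The 3′ minus 5′ log2 difference, a measure of RNA integrity, was 0.53 ± 0.01 (SD, n = 4) for the Actb control probe sets with cisplatin and 0.54 ± 0.03 in the controls (two-sided exact permutation test, p = 0.429). For Gapdh it was -0.15 ± 0.02 and -0.14 ± 0.02 (exact p = 0.543). The hybridisation spike-ins differed by -0.01 (exact p = 0.857) and the labelling spike-ins by 0.07 (exact p = 0.657). The 4 adjusted p-values of these controls were all 0.857.

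The comparison asked which transcripts of ES cells respond to cisplatin within 8 h. Cisplatin raised Plk2, a stress-responsive polo-like kinase, by 2.25 ± 0.15 (log2 fold change ± SE, 4 arrays against 4) and the antiproliferative gene Btg2 by 2.22 ± 0.12. Mdm2, which encodes the ubiquitin ligase that restrains p53, rose by 1.48 ± 0.12 and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 1.22 ± 0.12. On the lower side, Chac1, a glutathione-degrading enzyme, fell by 1.74 ± 0.15 on the log2 scale, and Gli2, a transcription factor of Hedgehog signalling, fell by 1.42 ± 0.06. The mitotic kinase gene Plk1 and the pluripotency gene Nr0b1 fell by less, at -0.77 ± 0.05 and -0.66 ± 0.07.

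Of the 17098 genes tested, 1989 were higher and 1314 lower with cisplatin at an adjusted p under 0.05 (limma), which is 19.3% of the genes. Of these, 150 genes were higher and 32 lower by at least 2-fold. The 4 values of one group lay above the 4 of the other for 4155 genes, or 24.3%, where chance gives 2.86%. Higher genes made up 60.2% of the calls. Centring each array on its median over the tested genes, which differed by 0.13 between the groups, moved the median change of all genes from 0.01 to -0.12 and the calls to 1087 higher and 3925 lower, or 21.7% higher. Centring thus lowers every change by about 0.13, while genes above the median expression differed by 0.04 on average between the groups. Calls that centring ends or adds below carry this shift.

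The largest increase was that of Synm, which encodes the intermediate filament protein synemin, at 2.45 ± 0.22 (adjusted p = 7.4e-05). Its log2 level was 6.99 ± 0.26 (SD, n = 4) with cisplatin and 4.54 ± 0.48 in the controls. The melanocyte antigen gene Mlana rose by 2.10 ± 0.08 (adjusted p = 1.53e-06), the p53 relative Trp73 by 2.10 ± 0.14 and Rtkn by 2.08 ± 0.13. Ephx1, which encodes microsomal epoxide hydrolase, rose by 2.06 ± 0.16, and Zfp750, a regulator of epidermal differentiation, by 2.01 ± 0.14. Trp73, Rtkn and Zfp750 were low in the controls, at 3.39, 3.60 and 3.88 against 3.10 for background probes.

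Among the genes that fell most after Chac1 were the kinase gene Camk1d at -1.60 ± 0.12, the guidance cue gene Ntn1 at -1.46 ± 0.06 and the zinc finger gene Bnc2 at -1.41 ± 0.05. The repressor gene Klf12 changed by -1.33 ± 0.12, Zfp407 by -1.30 ± 0.10 and Mirg, a noncoding RNA of an imprinted cluster, by -1.26 ± 0.09. Their adjusted p-values lay between 1.33e-06 for Bnc2 and 6.85e-05 for Klf12 and Chac1. The genes Camk1d, Ntn1, Gli2, Bnc2, Klf12 and Zfp407 are each over 100 kb long in the mouse reference annotation, whereas Chac1 spans 3.09 kb and Mirg 14.5 kb. Without genes over 100 kb, a choice made after the data were seen, 728 genes were lower and 3 of them by at least 2-fold.

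Of the 34 p53 target genes measured, 29 were higher, none was lower and 5 did not pass the test; adjusted over the list alone, 32 were higher. Against all other genes the list gave an adjusted p of 8.72e-22 by camera with a preset correlation of 0.01, and an adjusted p = 0.166 with an estimated correlation. The median change was 1.01, and besides Plk2, Btg2 and Ephx1 the list held Phlda3, a p53-induced repressor of Akt, at 1.64 ± 0.12 (adjusted p = 3.65e-05). The mean over the list was 8.39 ± 0.11 (SD, n = 4) with cisplatin and 7.45 ± 0.15 in the controls, and single arrays ranged from 8.27 to 8.52 and from 7.28 to 7.57. Trp53 itself was not analysed here.

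**Figure D1:**
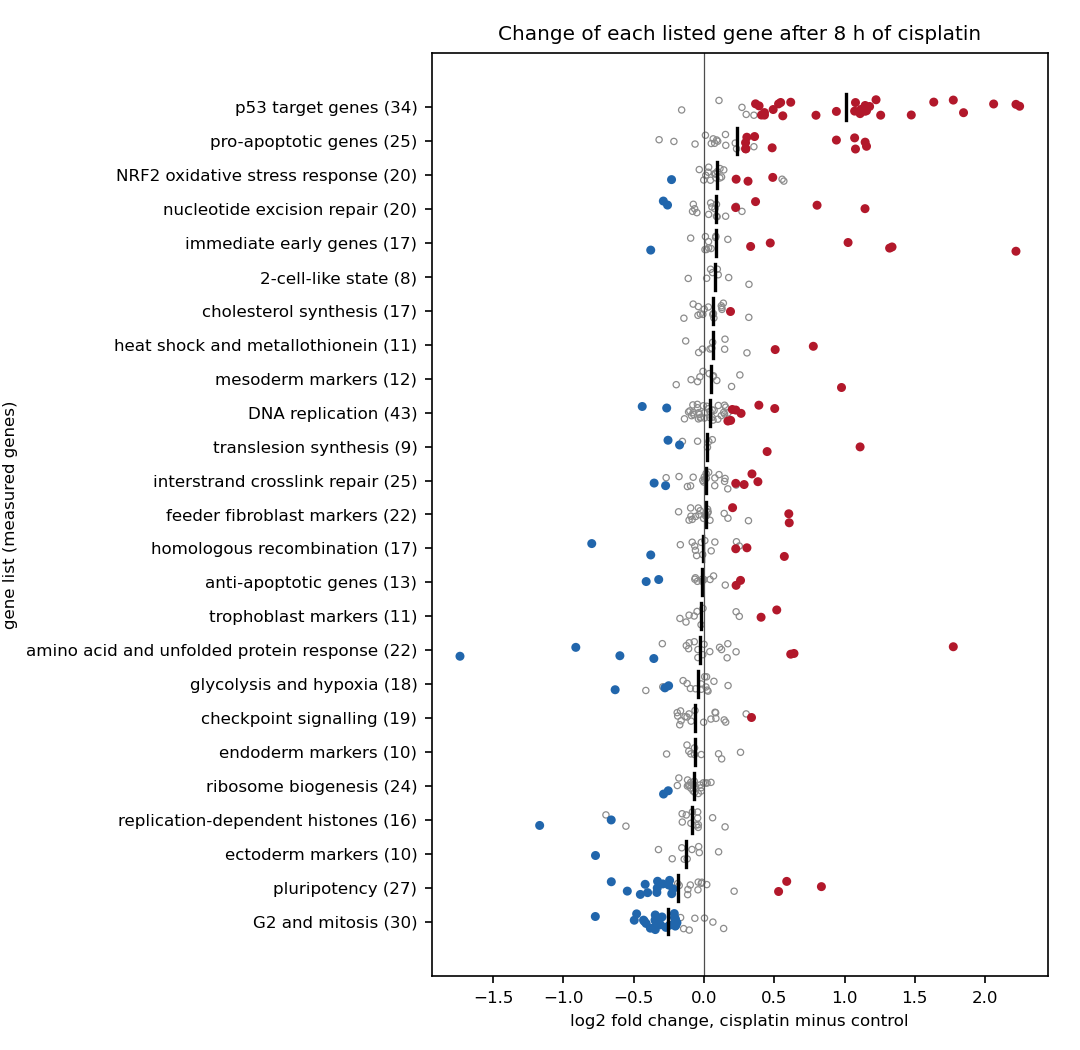
Log2 fold change (cisplatin minus control, x axis) of each measured gene in the 25 gene lists (y axis, number of measured genes in parentheses), ordered by median. Filled points passed limma's adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars mark list medians, which run from -0.26 for G2 and mitosis to 1.01 for p53 targets.

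Of 25 pro-apoptotic genes measured, 11 were higher and none lower (12 higher and 1 lower adjusted over the list alone), with a median of 0.23. Camera gave the list an adjusted p of 0.000207, and adjusted p = 0.0763 with an estimated correlation. Bbc3, which encodes the BH3-only protein PUMA, rose by 1.15 ± 0.15, the death receptor gene Fas, below background in the controls at 3.03, by 1.08 ± 0.11 or more, and the apoptosome gene Apaf1 by 1.07 ± 0.10. Bcl2l11, which encodes BIM, rose by 0.36 ± 0.06, though not when the probe set with the largest variance stood for the gene (0.26, adjusted p = 0.177). The p53 list shares 6 of its members; of the 19 others, 6 were higher and none lower, with a median of 0.15 (camera p = 0.010, and p = 0.0313 with an estimated correlation).

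The 13 anti-apoptotic genes went both ways, with 2 higher and 2 lower (the same counts adjusted over the list alone) and a camera adjusted p of 0.741. Birc6, an inhibitor of apoptosis, fell by 0.41 ± 0.05 on the log2 scale, while the co-chaperone genes Bag4 and Bag1 were higher by 0.26 ± 0.06 and 0.23 ± 0.06. Both calls were lost after centring the arrays (adjusted p = 0.128 and 0.220), and that of Bag1 also without cisplatin replicate 4 or 5 or control replicate 3 (adjusted p = 0.0522, 0.0509 and 0.0545). Cflar, which encodes the caspase-8 inhibitor FLIP, was at -0.32 ± 0.07 by its brightest probe set and at 0.42 by its most variable one, so its direction is not settled.

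Several DNA repair genes were higher and others lower. The p53 list shares 3 measured genes with the excision repair list, among them Ercc5 and Xpc, and 1, Polk, with the translesion synthesis list. In nucleotide excision repair 4 of 20 genes were higher and 2 lower (6 and 2 adjusted over the list alone): the endonuclease gene Ercc5 rose by 1.15 ± 0.09, Uvssa by 0.80 ± 0.12, Xpc by 0.37 ± 0.09 and Gtf2h5 by 0.23 ± 0.06, while Rad23b and Mnat1 changed by -0.29 ± 0.07 and -0.26 ± 0.06. Of the 25 genes of interstrand crosslink repair, 4 were higher and 2 lower, with Slx4 at 0.38 ± 0.08, Fancb at 0.34 ± 0.08, Dclre1a at 0.29 ± 0.07 and Rad51c at 0.23 ± 0.06 against Fancm at -0.35 ± 0.08 and Fancc at -0.27 ± 0.07. Among 9 genes of translesion synthesis the polymerase gene Polk rose by 1.11 ± 0.11 and Rev1 by 0.45 ± 0.09, while Rev3l and Polh were at -0.26 ± 0.07 and -0.17 ± 0.05. In homologous recombination 3 of 17 genes were higher (4 adjusted over the list alone) and 2 lower: Rad51d was at 0.57 ± 0.11, Rad52 at 0.31 ± 0.07 and Rad51c as above, while Rad51b, a gene of 551 kb, changed by -0.80 ± 0.11 and Bard1 by -0.38 ± 0.05. Of 19 checkpoint genes only Rad1 passed the test, at 0.33 ± 0.05, and Rad17 was at -0.16 ± 0.05 (adjusted p = 0.0636). Rad17 did pass after centring, without dim genes, with an intensity trend and with an ordinary t statistic (adjusted p = 0.00653, 0.0217, 0.0162 and 0.0415).

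The DNA replication list had 7 of 43 genes higher and 2 lower. Gins3 rose by 0.50 ± 0.08, the cyclin gene Ccne2 by 0.39 ± 0.06 and Rrm2, a subunit gene of ribonucleotide reductase, by 0.26 ± 0.06, whereas Pola1, the catalytic subunit gene of polymerase alpha, fell by 0.44 ± 0.07 on the log2 scale and Prim2 was at -0.27 ± 0.07. Counts adjusted over the list alone were equal for crosslink repair, translesion synthesis, checkpoint signalling and replication. Camera adjusted p-values for the 6 repair, checkpoint and replication lists ran from 0.253 for excision repair to 0.973 for translesion synthesis. By fry, which does not compare a list with other genes, excision repair and replication passed (adjusted p = 0.000711 and 0.00524). Excision repair without the 3 genes shared with the p53 list was not tested. The mean over the excision repair list was 8.12 ± 0.03 (SD, n = 4) with cisplatin and 7.98 ± 0.02 in the controls (exact permutation p = 0.0286). The list medians of excision repair, crosslink repair and replication were 0.08, 0.02 and 0.04, and turned to -0.05, -0.11 and -0.09 when arrays were centred on their median. For homologous recombination the median of -0.01 and the mean of 0.00491 differed in sign.

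Several of these calls were close to the threshold. Centring, which lowers every change by 0.13, ended several calls of higher genes. They were those of Slx4, Fancb, Dclre1a, Rad51c, Rad52, Xpc, Gtf2h5 and Rrm2, with adjusted p-values of 0.0546, 0.0807, 0.133, 0.277, 0.0903, 0.0744, 0.308 and 0.113. Another choice of probe set ended those of Rad23b and Fancm (most variable probe set, adjusted p = 0.453 and 0.521) and of Rad52, Fancc, Rev3l and Dclre1a (mean of the probe sets, adjusted p = 0.245, 0.354, 0.282 and 0.362). It also ended those of Polh and Rrm2 (most variable, 0.0560 and 0.0565) and of Polh, Gtf2h5 and Fancm (mean, 0.105, 0.0606 and 0.0855). The call of Xpc was lost without cisplatin replicate 5 or 6 (highest adjusted p = 0.0648), that of Gtf2h5 without cisplatin replicate 3, 4 or 5 or control replicate 3 or 5 (highest 0.0897), and that of Dclre1a without cisplatin replicate 4 or 6 or control replicate 3 or 6 (highest 0.0598). For Rad51c the arrays were cisplatin 3, 5 and 6 and control 3, 4 and 6 (highest 0.0915), for Fancc cisplatin 3, 4 and 5 and control 5 and 6 (highest 0.0671), and for Rev3l cisplatin 4 and 5 and control 3 and 4 (highest 0.0738). Prim2 lost its call without cisplatin replicate 5 or 6 or control replicate 3, 4 or 5 (highest 0.0625), and Polh without any array but cisplatin replicate 6 (highest 0.122).

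Of 30 genes of G2 and mitosis measured, 23 were lower, none higher and 7 did not pass the test (25 lower and 1 higher adjusted over the list alone), with a median of -0.26. Camera gave an adjusted p of 3.14e-14, and adjusted p = 0.0763 with an estimated correlation. After Plk1 (1.71-fold lower, adjusted p = 2.58e-05), the spindle kinase gene Aurka changed by -0.50 ± 0.05, the spindle assembly factor gene Tpx2 by -0.48 ± 0.06 and the kinesin gene Kif11 by -0.42 ± 0.05. The mean over the list was 9.74 ± 0.02 (SD, n = 4) with cisplatin and 10.01 ± 0.03 in the controls.

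Of the 16 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 2 were lower (also adjusted over the list alone), H1f2 at -1.17 ± 0.19 and H4c9 at -0.66 ± 0.17, while H2bc4 was at -0.70 ± 0.26 (adjusted p = 0.0944) and H3c7 at -0.16 ± 0.06 (adjusted p = 0.121). The list median was -0.09 with a camera adjusted p of 0.0436, and adjusted p = 0.630 with an estimated correlation. The list's call was lost without cisplatin replicate 3 or 6 or control replicate 4 or 5 (adjusted p = 0.128, 0.0637, 0.0846 and 0.111) and after centring or without dim genes (adjusted p = 0.0942 and 0.204). The call of H4c9 was lost without control replicate 4 or 5 (adjusted p = 0.0606 and 0.0631). By contrast, H2bc4 passed after centring or without control replicate 6 (adjusted p = 0.0269 and 0.0467). H3c7 passed after centring or with quantile normalization applied again (adjusted p = 0.00639 and 0.0437).

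The pluripotency list divided. Of 27 genes, 13 were lower, 3 higher and 11 did not pass the test (13 lower and 4 higher adjusted over the list alone), and the median was -0.19. Camera gave the list an adjusted p of 0.000207, and adjusted p = 0.0843 with an estimated correlation. The orphan receptor genes Nr0b1 and Esrrb changed by -0.66 ± 0.07 and -0.55 ± 0.07, and Fbxo15 by -0.42 ± 0.07. The higher genes were Nodal, a signal of the TGF-beta family, at 0.84 ± 0.09, and its antagonists Lefty1 and Lefty2, named after their values were seen, at 0.59 ± 0.13 and 0.53 ± 0.10. Of the core factors, Nanog was at -0.25 ± 0.06 (adjusted p = 0.0210), Sox2 at -0.12 ± 0.05 (adjusted p = 0.134) and Pou5f1 at -0.04 ± 0.06 (adjusted p = 0.674), with Pou5f1 at 12.19 ± 0.06 (SD, n = 4) on the cisplatin arrays. The call of Nanog was lost without cisplatin replicate 4 or 5 or control replicate 3 or 6 (adjusted p = 0.0587, 0.0603, 0.0563 and 0.0517). After centring, which lowers every change by 0.13, Sox2 and Pou5f1 passed the test, at -0.25 and -0.17 (adjusted p = 0.00702 and 0.0443). At its unchanged -0.12, Sox2 also passed without dim genes, with an intensity trend and with an ordinary t statistic (adjusted p = 0.0427, 0.0108 and 0.0276).

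**Figure D2:**
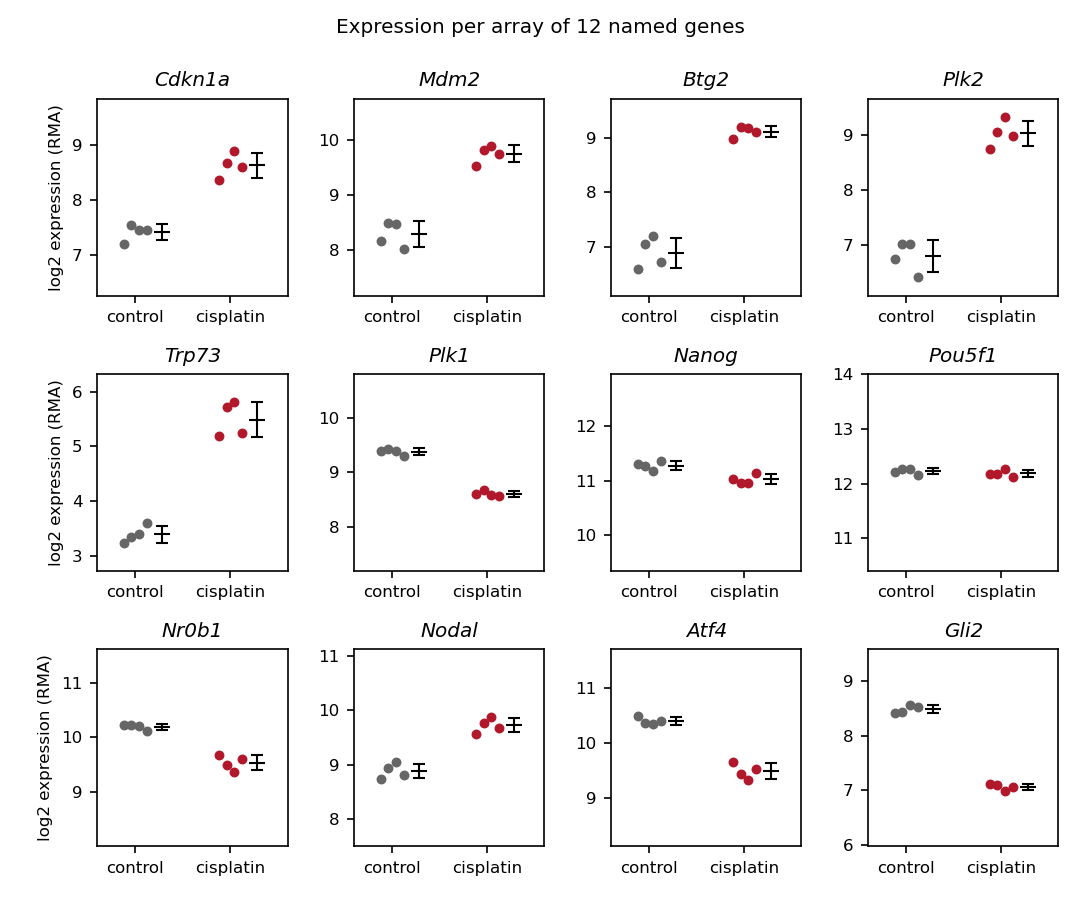
Log2 expression (RMA, y axis, every panel spanning the same range) of 12 named genes on each of the 4 control arrays (grey) and 4 cisplatin arrays (red); the points of a group run from replicate 3 at the left to 6, and the black mark and bar give the mean ± SD. The groups do not overlap for Cdkn1a, Mdm2 or Btg2, and they do for Pou5f1, at 12.23 ± 0.06 in the controls and 12.19 ± 0.06 with cisplatin.

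Few markers of differentiated and other cell types passed the test, and many lay below the background cut of 3.10 in both groups, where a fall is harder to see. They were 5 of 10 for endoderm, 5 of 12 for mesoderm, 4 of 10 for ectoderm, 3 of 11 for trophoblast and 11 of 22 for fibroblasts. None of 10 endoderm markers passed the test, where the highest-ranked, Hnf4a, was at 0.26 ± 0.09 (adjusted p = 0.0645). Among 12 mesoderm markers Mesp2 rose by 0.97 ± 0.16, while the related Mesp1 was at 0.26 ± 0.11 (adjusted p = 0.146). Among 10 ectoderm markers the neural gene Pax6 fell by 0.77 ± 0.16 on the log2 scale, and Otx2 was at -0.32 ± 0.14 (adjusted p = 0.150), though it passed after centring (adjusted p = 0.0349). The trophoblast list had 2 of 11 genes higher, Ascl2 at 0.52 ± 0.13 and Krt7 at 0.41 ± 0.10. The cells had been kept on feeder cells before gelatin, and 3 of 22 fibroblast markers were higher, Thy1 at 0.61 ± 0.15, Mmp2 at 0.60 ± 0.08 and Fbln2, below background in both groups, at 0.20 ± 0.05. The mean over the fibroblast list was 4.00 ± 0.17 (SD, n = 4) with cisplatin and 3.93 ± 0.12 in the controls (exact permutation p = 0.543). No count of these 5 lists changed when adjusted over the list alone, and camera adjusted p-values ran from 0.0958 for ectoderm to 0.973 for trophoblast. The ectoderm list passed without control replicate 6 and without genes over 100 kb (adjusted p = 0.0389 and 0.0460). The trophoblast median of -0.02 and mean of 0.08 differed in sign. The call of Thy1 was lost without control replicate 3 (adjusted p = 0.0519), that of Ascl2 without cisplatin replicate 4 or 5 or control replicate 3 (highest 0.0559), and that of Fbln2 without cisplatin replicate 5 or 6 or control replicate 3, 4 or 5 (highest 0.0728). Those of Krt7 and Fbln2 were also lost after centring (adjusted p = 0.0600 and 0.351).

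Of 17 immediate early genes 6 were higher, 1 lower and 10 did not pass the test (the same adjusted over the list alone), with a median of 0.08 that turned to -0.05 when arrays were centred on their median. Camera gave an adjusted p of 0.0436, and adjusted p = 0.356 with an estimated correlation. The mean change was 0.40, since a few genes moved far. Besides Btg2, the AP-1 component genes Fos, Fosl1 and Jun rose by 1.34 ± 0.18, 1.32 ± 0.20 and 1.03 ± 0.13. The lower gene was Klf6, named after its value was seen, at -0.38 ± 0.10, and its call was lost without cisplatin replicate 6 or control replicate 3, 4 or 5 (highest adjusted p = 0.0577) and with its most variable probe set (0.0503). The list's call was lost without cisplatin replicate 3 or control replicate 5 or 6 (adjusted p = 0.0918, 0.0734 and 0.0506), without dim genes (0.197), with array weights (0.0517) and without genes over 100 kb (0.0639).

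The list of amino acid and unfolded protein response genes held large changes in both directions, with 3 of 22 genes higher (4 adjusted over the list alone) and 4 lower, and a camera adjusted p of 0.724. The stress-response transcription factor gene Atf4 fell by 0.91 ± 0.08 on the log2 scale (adjusted p = 5.78e-05), along with Chac1, the chaperone-associated gene Herpud1 (-0.60 ± 0.12) and the amino acid transporter gene Slc7a5 (-0.36 ± 0.07). The higher genes were Ddit4 at 1.77 ± 0.20 and Sesn2 at 0.62 ± 0.10, both also on the p53 list, and Cebpb at 0.64 ± 0.11.

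Other stress and metabolic lists did not pass the test by camera, though 3 of them did under some other settings. The heat shock list had Hspa1b and Dnajb1 higher, by 0.78 ± 0.13 and 0.51 ± 0.05, among 11 genes (3 adjusted over the list alone; camera adjusted p = 0.0958). Of 20 NRF2 targets 3 were higher, Nqo1 at 0.49 ± 0.10, Srxn1 at 0.31 ± 0.07 and Gclc at 0.23 ± 0.05, and the exporter gene Abcc1 was lower at -0.23 ± 0.05 (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0703). The calls of Srxn1 and Gclc were lost after centring (adjusted p = 0.0751 and 0.205), and those of Srxn1 and Abcc1 with their most variable probe sets (adjusted p = 0.653 and 0.293). Of 18 glycolysis and hypoxia genes, Hk2, which encodes hexokinase 2, fell by 0.63 ± 0.06 on the log2 scale, and Pdk1 and Pfkp were also lower at -0.28 ± 0.06 and -0.25 ± 0.07 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0627). Pfkp lost its call without any array but cisplatin replicate 4 and control replicate 5 (highest adjusted p = 0.0696). The glycolysis list passed with the mean of the probe sets or the most variable one (adjusted p = 0.0232 and 0.0189), the NRF2 list over all probe sets or with an intensity trend (0.0120 and 0.0202), and the heat shock list likewise (0.00563 and 0.0370). Leaving out 1 array gave camera adjusted p-values from 0.0218 to 0.169 for the glycolysis list and from 0.0415 to 0.229 for the NRF2 list. Of 17 cholesterol synthesis genes only Stard4 passed the test, at 0.19 ± 0.06, and none did adjusted over the list alone; its call was lost without any array but control replicate 6 (highest adjusted p = 0.111), with the mean of its probe sets or the most variable one (0.128 and 0.153) and after centring (0.50).

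Of 24 ribosome biogenesis genes 2 were lower and 22 did not pass the test, with a median of -0.07, a camera adjusted p of 0.00980, and adjusted p = 0.580 with an estimated correlation. Wdr43, a factor of the small ribosomal subunit, and Ubtf, a transcription factor of RNA polymerase I, fell by 0.29 ± 0.06 and by 0.25 ± 0.06 on the log2 scale (also 2 lower adjusted over the list alone), and Bop1 and Polr1a were at -0.19 ± 0.08 and -0.12 ± 0.05 (adjusted p = 0.139 and 0.176). None of 8 genes of the 2-cell-like state passed the test, over all genes or adjusted over the list alone, where Zfp352 was at 0.32 ± 0.17 (adjusted p = 0.254) and Tdpoz1 at -0.11 ± 0.11 (adjusted p = 0.554). Hprt, named in the label of the cells, was at 4.60 ± 0.37 (SD, n = 4) in the controls and 4.84 ± 0.16 with cisplatin (adjusted p = 0.373), and no unmodified cells were compared here. The labels do not say which part of the gene is altered, so this level neither checks nor contradicts the label.

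In all, 7 of the 25 lists passed camera's adjusted p of 0.05 with the preset correlation, and 0 did with an estimated correlation, where the smallest adjusted p was 0.0763 and 10 passed by fry. The list means differed between the groups with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give, for 13 of the 25 lists, with an adjusted exact p of 0.0549. They were 6 of the 7 lists that passed camera, and the excision repair, translesion synthesis, replication, mesoderm, NRF2, heat shock and glycolysis lists, which did not. For the histones, the remaining list that passed camera, the exact p was 0.114.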

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

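Within a group of 4 arrays, single values stood far from the other 3 for 7 of the 298 groups of values examined, where chance alone gives about 14.9, or 1 in 20. Mesp2 was at 4.81 on cisplatin replicate 3 against 5.47 to 5.60 on the other cisplatin arrays, and Mesp1 at 4.12 on cisplatin replicate 4 against 3.73 to 3.79. Fos was at 4.76 on control replicate 6 against 5.41 to 5.52, and Xpc at 6.45 on control replicate 3 against 6.77 to 6.79. Nsdhl was at 8.10 on cisplatin replicate 6 against 8.22 to 8.23, and Tcstv1 at 3.29 on cisplatin replicate 3 against 3.66 to 3.72. The 3′ minus 5′ difference of Gapdh was -0.176 on cisplatin replicate 3 against -0.137 to -0.131.

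Among the 15588 probe sets with no gene listed, which the comparisons by gene leave out, 500 were higher and 704 lower with cisplatin at an adjusted p under 0.05 (limma over all probe sets other than controls), 38 and 13 of them by at least 2-fold. The largest changes among them were 2.36 ± 0.19 and 2.20 ± 0.18 upwards, and -1.50 ± 0.09 and -1.28 ± 0.10 downwards.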

How the results depend on the processing

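The choices without genes over 100 kb and without probe sets that can match several transcript families were made after the data were seen. The 4 counts of genes and the count of lists stayed within 1.5 times their value with probe sets of largest variance, quantile normalization applied again, dim genes left out, an intensity trend or array weights, and the gene counts also with an ordinary t statistic, for which the lists were not run. Leaving out 1 array gave 1580 to 1871 genes higher, 1037 to 1246 lower, 136 to 183 higher and 27 to 37 lower by 2-fold, and 5 to 9 lists. The mean of all probe sets of a gene left 16 genes lower by 2-fold; averaging probe sets that differ in brightness shrinks a change, but the cause was not tested. Over all probe sets, counted singly, 2814 were lower, 237 higher by 2-fold and 62 lower by 2-fold, since there are more probe sets than genes. Centring each array on its median gave 1087 higher, 3925 lower and 55 lower by 2-fold, since it takes 0.13 more from the cisplatin arrays. The threshold of 0.01 gave 1113 higher and 742 lower. With an estimated correlation 0 lists passed. The estimate was 0.435 for p53 targets but 0.0120 for pro-apoptotic genes, close to the preset 0.01. For the pro-apoptotic list the unadjusted camera p still went from 2.49e-05 to 0.00611. The size of its correlation therefore does not account for the loss, and what else the setting changes was not tested. A call lost with an estimated correlation is thus not by itself a sign of correlated genes. Without genes over 100 kb 728 were lower and 3 lower by 2-fold, since those genes were removed.

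Cflar turned to 0.0903 with the mean of its probe sets and to 0.421 with the most variable one, and the immediate early median turned to -0.0483 after centring; the cause was not tested for Cflar. Of the 109 named genes that were called, 74 kept their direction and call in every alternative that tested them, and 35 did not; 18 lost the call without some array and 16 after centring. The ordinary t statistic ended the calls of Ascl2, Fancc, H4c9, Klf6, Krt7, Rad51c, Rev3l, Thy1 and Xpc (highest adjusted p = 0.0912), and the intensity trend those of Fancc and Polh (0.0519 and 0.0868). Over lists and alternatives, 484 values kept direction and call, 25 gained a call, 22 lost one and 16 of lists not called moved. The replicate numbers were tested as pairs: deviations of same-numbered arrays correlated at 0.199, 0.181, 0.200 and 0.0649, and 7 of the 8 arrays correlated best with their own number, a hint from the data and not from the design. With the replicate block 2111 genes were higher, 1336 lower, 150 and 32 by 2-fold, and 10 lists passed; 2980 of the 3303 calls were shared with the 3447 under the block. Of the named genes, the block called Otx2, H2bc4, Mesp1, Tubb3 and Krt18 (adjusted p = 0.00665, 0.00686, 0.0216, 0.0305 and 0.0336) and ended the calls of Gtf2h5, Polh and Stard4 (0.0514, 0.0725 and 0.0673). Signal limits the dim genes: 78 of 5359 genes below background in both groups were called.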

Other observations

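The tests of the lists of ATF4 targets, Hedgehog and Wnt genes and epithelial genes, of RNA quality and of Pou5f1 were chosen after the results were seen; the others were planned before. Targets of ATF4, which activates genes of amino acid supply, were listed because Atf4 and Chac1 were lower; neither is on the list. Of 25 measured, 10 were lower and none higher, among them the proline synthesis gene Aldh18a1 at -0.58 ± 0.08, the mitochondrial enzyme gene Pck2 at -0.57 ± 0.09, Stc2 at -0.72 ± 0.13 and the amino acid transporter genes Slc7a1, Slc1a5 and Slc3a2 at -0.44 ± 0.06, -0.41 ± 0.08 and -0.28 ± 0.05. With its most variable probe set Slc1a5 did not pass the test (adjusted p = 0.0699). The known target Asns was at -0.04 ± 0.07 (adjusted p = 0.735) and Trib3 at -0.07 ± 0.10 (adjusted p = 0.710). Of the 16 targets on no earlier list 9 were lower, with a median of -0.25 (camera p = 1.23e-07, and p = 0.0534 with an estimated correlation), and 0% of 10000 random lists matched on gene length and expression had a median as low. Lower Atf4 mRNA may have been followed by lower output of some of its targets, a hypothesis that the levels of Asns and Trib3 limit.

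Of 28 Hedgehog and Wnt signalling genes 11 were lower and 1, Smo, was higher at 0.27 ± 0.07 (not after centring, adjusted p = 0.128, nor without cisplatin replicate 4 or control replicate 3 or 6, highest 0.0532, nor with the mean of its probe sets or the most variable one, 0.0730 and 0.30), with a median of -0.10 (camera p = 0.000128, and p = 0.00500 with an estimated correlation). Gli3 changed by -0.90 ± 0.07, Znrf3 by -0.75 ± 0.05, Tcf7l1 by -0.72 ± 0.09 and Ptch1, itself a Hedgehog target, by -0.67 ± 0.07, while Gli1 was at 0.16 ± 0.12 (adjusted p = 0.408). These genes are long, with a median of 64.9 kb, and 3.00% of 10000 random lists matched on length and expression had a median as low, so a change beyond that of other long genes cannot be told apart from their length here. A list of epidermal and epithelial barrier genes, tested because Zfp750 was higher, had 8 of 38 genes higher, such as Grhl3 at 0.60 ± 0.06 and Evpl at 0.73 ± 0.13, and 3 lower, such as Esrp1 at -0.58 ± 0.11. As a list it did not pass the test (camera p = 0.158, and p = 0.297 with an estimated correlation).

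The 8 arrays split into 4 and 4 in 35 ways. Only the real split (1 of 35) gave as many genes higher (1989), lower (1314), higher by 2-fold (150) or lower by 2-fold (32). The highest count in the other splits was 0 each time, which argues against chance for the 4 counts. As 1 of 35 is the smallest share these splits can give, chance is not excluded. A difference between the groups other than the drug would pass this test too. As many lists as the real 7 passed in 6 of the 35 splits, with up to 11 in another split. Apart from the real one, these splits all kept all but 1 array of each group together, so they still carried part of the contrast. Splits that mixed the groups evenly gave at most 5 lists. The 6 of 35 is therefore not a measure of chance alone, and chance is not excluded for the number of lists.

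Long genes were more often lower than short ones: across 16937 genes, which are not independent replicates, Spearman's rho between log2 fold change and gene length was -0.249, and -0.246 without the 32 genes lower by 2-fold, and 29 of those 32 were over 100 kb, or 90.6% against 12.5% of the tested genes. Of 471 genes over 300 kb 24.4% were lower and 1.27% higher, and of 5108 under 10 kb 108 were lower and 666 higher; among genes above the median expression, 72.7% of the 99 over 300 kb were lower and 5.05% higher, against 4.25% and 24.2% under 10 kb. Expression level as the cause is argued against by rho under -0.1 in 3 of the 4 expression quartiles (the dimmest, at -0.03, excepted), and RNA degradation by 3′ minus 5′ differences that moved by no more than -0.0130 between groups. The median difference between genes over 100 kb and under 10 kb was -0.13. The size of 0.132 was reached by 1 of 35 splits, the real one, with 0.112 as the highest of the others. The split at 0.112 kept all but 1 array of each group together, and splits that mixed the groups evenly reached at most 0.0277. As 1 of 35 is the smallest share these splits can give, chance is argued against but not excluded. A candidate explanation is that platinum lesions stop RNA polymerase more often in long genes, and another is a shorter half-life of transcripts from long genes. Neither was tested, and both stay open.

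Of 30 mitotic genes 23 were lower while replication genes went both ways, and the mitotic list's call was lost with an estimated correlation (adjusted p = 0.0763). Gene length and expression level are argued against as the cause, since 0% of 10000 random lists matched on both had a median as low as -0.26, with the lowest at -0.09. Whether fewer cells were in mitosis or each cell made less of these transcripts was not tested, and both could give the values.

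Of 27 pluripotency genes 13 were lower and 3 higher, and the list's call was lost with an estimated correlation (adjusted p = 0.0843). Length and expression level are argued against in the same way, with 0% of 10000 matched lists at or below the median of -0.19. A larger share of other cells that lack all these transcripts would lower them alike, but Nodal, Lefty1 and Lefty2 rose by 0.84, 0.59 and 0.53. Other cells that make these 3 transcripts could raise them. Their rise therefore argues, as the only cause, only against cells that lack them. The 95% interval of the Pou5f1 change, -0.167 to 0.0814, clears the list's median only narrowly. Some markers of other cells were higher (Mmp2, Thy1, Ascl2 and Krt7, by 0.60, 0.61, 0.52 and 0.41) and Pax6 was lower. As lists, the fibroblast and trophoblast markers did not pass camera (adjusted p = 0.905 and 0.973). A part played by other cells stays open. The treatment stays open as a cause that acts on some of these genes, which may be tied to p53 or to growth, and neither was tested.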
